A study of Homo sapiens with 7 samples.

How the data were processed

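The series holds 7 samples of MCF-7 cells, namely FOXN3, SIN3A and input chromatin immunoprecipitation (1 each) and FOXN3 and IgG iRIP-seq (2 replicates each). The RNA libraries were made with a small RNA kit and sequenced in pairs, per the labels' protocols. The submitters' processing notes name Bowtie2, TopHat2, MACS2 and ChIPseeker and the builds hg19 and hg38 without saying which step used which. Versions, filters, the handling of duplicate reads and the use of IgG in calling are not given in the sources used here. The chromatin immunoprecipitation samples were not analysed here.

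The deposited lists used were a Piranha peak list and a CIMS list for replicate 1 and for replicate 2. Neither the list names nor the headers name an antibody, so no list was assigned to FOXN3 or IgG. Lists were called per replicate number, per the deposited lists. For Piranha, the authors give tags per bin as a signal, per the file headers, and the values show bins of 50 bases, with tags averaged over the bins of a merged peak. The peak p-value is as the authors' caller gave it, per the file headers. For CIMS, the deposited count is the number of tags that carry the mutation. The deposited coverage is the number of tags over the site, and the q-value is the caller's false discovery rate, per the file headers of replicate 2. The replicate 1 list has no header and the same layout. In both CIMS lists 1 base was listed under different mutation types, and it was counted once, with the type that had more mutated tags. Scores were used to describe, rank, weight and filter features within a list, to compare shared with unshared peaks of a list, and to correlate identical peaks between the Piranha lists. Processing affects the values in known ways: a threshold on tags favours abundant RNAs, removal of reads with the same start would compress high bins, and alignment decides whether a read lies in a gene or in its pseudogene copy.

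Genes came from a table of 59716 gene bodies of GRCh38.p14 with biotypes and without strand or exons. The build was checked by shifting the features. At their own positions 99.5%, 99.3%, 95.7% and 96.2% of the features on the nuclear chromosomes overlapped a gene, in the order Piranha replicates 1 and 2 and CIMS replicates 1 and 2. After a shift of 1 Mb up or down the shares ranged from 60.7% to 68.9%. For genes under 1000 bases they were 5.68%, 5.34%, 8.32% and 8.75% unshifted and at most 0.403% after a shift. A feature was assigned to the overlapped genes of the leading class in the order mitochondrial, unplaced contig, small RNA, nuclear ribosomal RNA, pseudogene, protein-coding, lncRNA and other, regardless of strand. With neither exons nor a genome at hand, classes by exon, intron or UTR, bases and 5-mers at sites, same-strand assignment and placement in exons were not run, although they had been planned. Base positions of substitution sites are not reported here.

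Sharing between lists needed an overlap of at least 1 base on the same strand, or the same base for CIMS sites. Chance came from 1000 random placements of the other list's features within their own genes, or within 100 kb for features outside genes. Because gene bodies include introns, placement within 1000 bases of each feature was added after seeing the data, and for NEAT1 and MALAT1 it was kept inside the gene. Gene overlap was tested with two-sided Fisher's exact tests and preset lists with one-sided ones. Benjamini-Hochberg adjustment covered the 26 preset-list tests together and the 10 classes within a caller or replicate, and odds ratios have Woolf 95% intervals. Tags of shared and unshared peaks were compared with permutation tests of 100000 resamples. Shares have Wilson 95% intervals, which cover counting error only. The total depth per library is not given in the lists, so features that did not reach a list are not called absent.

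Named genes were set by a rule fixed before the data were examined. They are NEAT1, MALAT1, FOXN3, SIN3A, GATA3 and ESR1 whatever their values, the 10 genes and 10 lncRNA genes per caller with the most features in both replicates, up to 4 members per preset list chosen likewise, and the 5 shared features per caller with the highest lower score. Only 3 lncRNAs met the rule for Piranha, and 8 for CIMS. The 13 preset lists cover nuclear and chromatin lncRNAs, housekeeping small RNAs, mitochondrial transcripts, the SIN3A complex, luminal and oestrogen-response mRNAs, epithelial junction and mesenchymal transition mRNAs, ribosomal proteins, translation factors, paraspeckle and nuclear RNA-binding proteins, histones, heat-shock and folding proteins, cytoskeleton and glycolysis, and markers of blood, immune, stromal and endothelial cells. Alternatives covered overlap, strand, score, background, class order and placement.

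The procedures were tested on simulated data. With 30% of the 2248 Piranha peaks or of the 2843 CIMS sites copied into a randomly placed list, 31.9% and 30.04% were recovered as shared. For gene lists of 30 members among 900 genes, 4.0% of 200 lists passed at an odds ratio of 1 and 97.5% at an odds ratio of 5. Most preset lists had fewer members among the genes tested. For Piranha these were 8 for the heat-shock and protein-folding list and 12 for the cytoskeleton and glycolysis list. The simulated shares therefore give neither the power of the adjusted tests nor that of the tests of such smaller lists. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.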

Results

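The series profiled the forkhead factor FOXN3 and the corepressor scaffold SIN3A in MCF-7 cells, an established luminal breast cancer line. Chromatin immunoprecipitation sequencing was done once each for FOXN3, SIN3A and input DNA. RNA bound in FOXN3 or control IgG precipitates was read by improved RNA immunoprecipitation sequencing (iRIP-seq), which sequences RNA recovered with an antibody, in 2 replicates per antibody. Of these 7 samples, only the iRIP-seq part was analysed here, through 2 kinds of list per replicate number. Piranha peaks are bins of 50 bases with more tags than the caller's background allows. CIMS lists hold crosslink-induced mutation sites, single bases at which several tags carry the same kind of mutation. The lists carried a replicate number but no antibody, so FOXN3 was not compared with IgG, and a feature is a property of the list and not evidence of FOXN3 binding. The Piranha lists held 2248 and 2086 peaks and the CIMS lists 2843 and 2155 distinct sites in replicates 1 and 2. The sequencing depth of the libraries is unknown. The peaks had a median of 13 tags per bin in both replicates, as the authors' values, with 11 at the least and 41 and 39 at the most.

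The question of the iRIP-seq part was which RNAs, long noncoding RNAs (lncRNAs) in particular, come down with FOXN3, and the lists allow a narrower one: which RNAs recurred between replicates. The 10 genes with the most Piranha peaks in both replicates encode proteins of several compartments. CPS1, an enzyme of the urea cycle, carried 34 and 20 peaks in replicates 1 and 2, and FN1, which encodes fibronectin, carried 30 and 21. The catalytic sodium pump subunit ATP1A1 had 26 and 20 peaks, the nuclear pore glycoprotein gene NUP210 24 and 26, and the transferrin receptor gene TFRC 22 and 21. ITGA5, a subunit of the fibronectin receptor, had 22 and 24, the adhesion molecule gene L1CAM 22 and 22, and the collagen gene COL5A1 21 and 22. EEF2, the translocation factor of translation, had 18 and 22 peaks, and P4HB, a protein disulfide isomerase of the endoplasmic reticulum, 17 and 19. All peaks of ITGA5 also overlapped the gene body of GPR84-AS1, and some peaks of ATP1A1, COL5A1 and FN1 those of ATP1A1-AS1, LOC101448202 and the protein-coding gene ATIC, and the annotation used here had no strand to separate them.

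Of the 680 genes with a Piranha peak in replicate 1 and the 619 in replicate 2, 473 were the same, which is 69.6% of the former and 76.4% of the latter. The odds ratio for a gene to be hit in both was 30.5 (95% interval 24.1 to 38.5, two-sided Fisher's exact test, p = 7.05e-230) over the 2773 genes that any of the 4 lists hit. Genes are not independent replicates, so the p describes these lists.

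**Figure D1:**
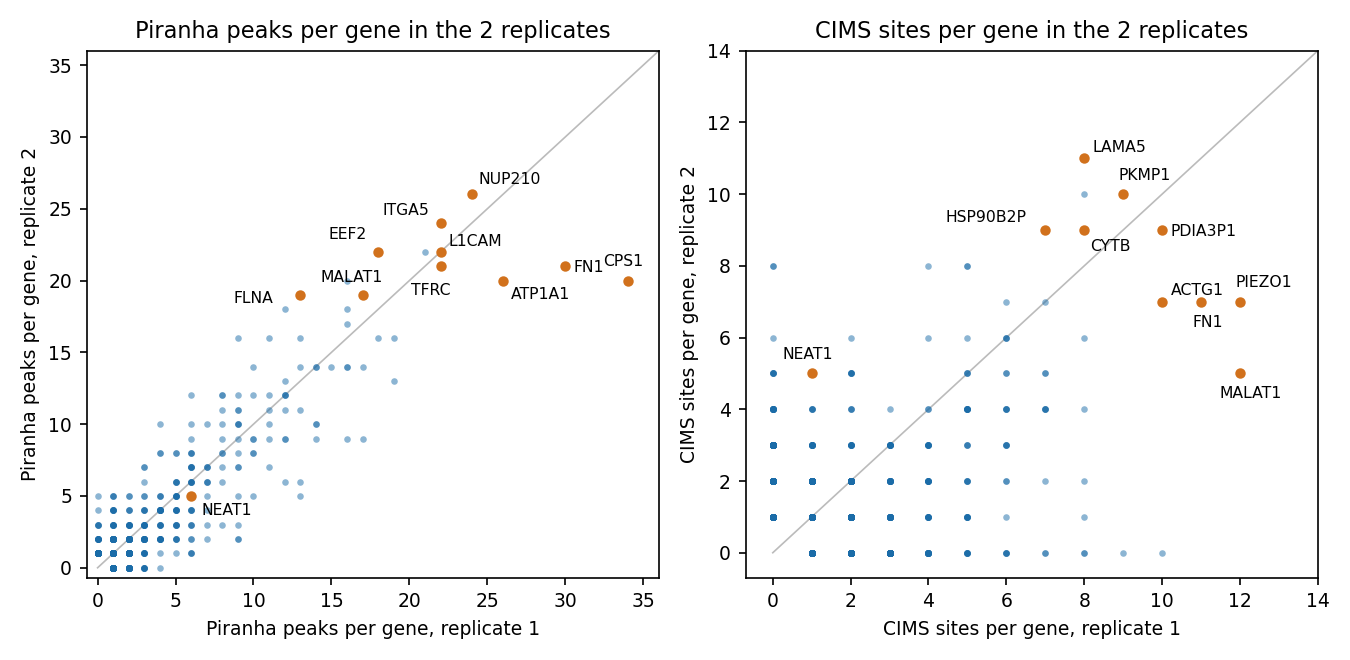
Number of Piranha peaks (left) and CIMS sites (right) per gene in replicate 1 (x axis) and replicate 2 (y axis), with 1 point per gene, the line of equal counts in grey and selected named genes in orange. CPS1, with 34 and 20 peaks, and NUP210, with 24 and 26, lie at the far end of the left panel, and NEAT1, with 6 and 5, lies among many other genes.

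The individual peaks recurred as well. The peak with the highest lower value lay in PSAP, which encodes the lysosomal protein prosaposin (GRCh38 chromosome 10, 71831101 to 71831150, minus strand), with 32 and 35 tags per bin. The next were in RN7SK, the noncoding 7SK RNA (chromosome 6, 52995851 to 52995900, plus strand, 33 and 29 tags), and in the cyclophilin gene PPIB (chromosome 15, 64160101 to 64160150, minus strand, 29 and 30 tags). BSG, which encodes basigin, had 28.5 and 29.5 tags (chromosome 19, 582501 to 582600, plus strand). The amino acid transporter gene SLC38A2 had 41 and 28 (chromosome 12, 46372501 to 46372550, minus strand). The table of genes used here gives gene bodies only, so exon, intron and UTR are not stated.

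In all, 1175 of the 2248 replicate 1 peaks overlapped a replicate 2 peak by at least 1 base on the same strand, which is 52.3% (Wilson 95% interval 50.2 to 54.3). In the other direction 56.1% did (53.9 to 58.2). Placing the replicate 2 peaks at random within their own genes gave 5.07% on average and 6.27% at the most in 1000 placements. The share was thus 10.3 times chance (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Placement within 1000 bases of each peak gave 6.07%, which left 8.61 times chance. Both placements can fall in introns, so peaks confined to exons would exceed chance even without recurring at the same positions. Exons were not at hand to measure this. Shared peaks were higher than unshared ones, with a mean of 15.3 ± 4.0 tags (SD, n = 1175) against 13.0 ± 2.89 (SD, n = 1073) in replicate 1. In replicate 2 the means were 15.0 ± 3.80 (SD, n = 1170) and 12.9 ± 2.90 (SD, n = 916). Both differences had a two-sided permutation p = 2e-05, the smallest that 100000 resamples can give. A peak near the lowest listed value of 11 tags reaches the other list less easily, so such a difference is partly built in. Over the 948 peaks with identical borders in both lists, tags correlated with a Pearson's r of 0.553 and a Spearman's rho of 0.419 (permutation p = 1e-05 each, the smallest possible). The comparison of tags and this correlation are across peaks, which are not independent replicates. The labels do not say that the replicates were separate cultures, so these values measure agreement between 2 lists that may be technical.

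**Figure D2:**
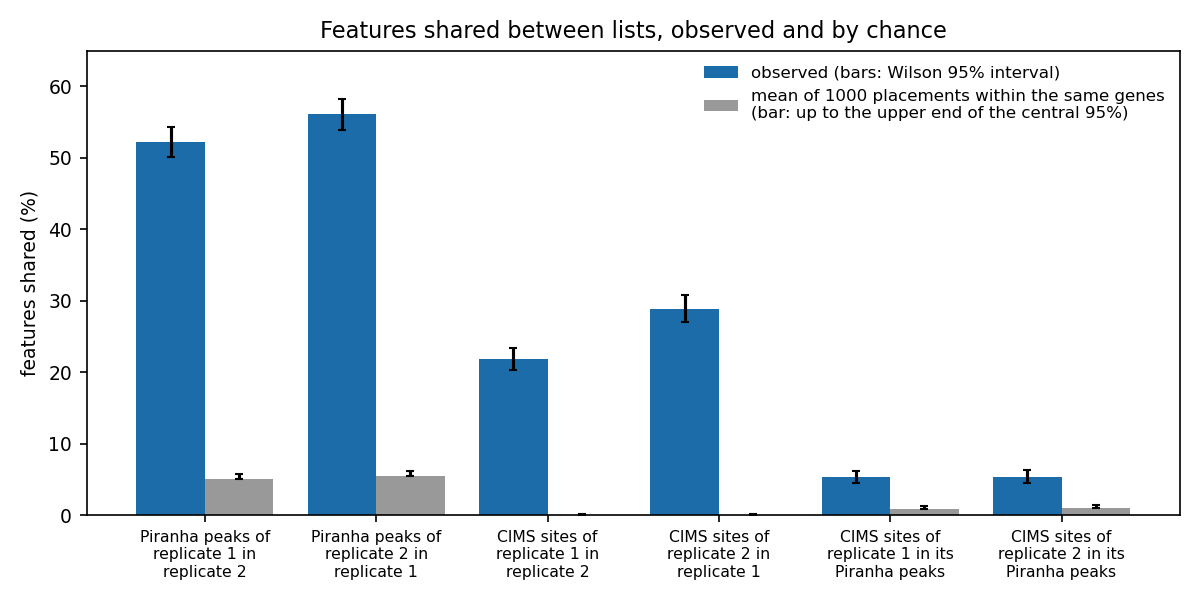
Share of features (y axis, percent) found in the other list, for Piranha peaks and CIMS sites in either direction and for CIMS sites inside Piranha peaks of the same replicate. Blue bars are the observed shares with Wilson 95% intervals, and grey bars are the means of 1000 random placements within the same genes with the upper end of the central 95% of placements. Replicate 1 peaks reached 52.3% against 5.07% by chance.

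Most features lay in protein-coding genes. These held 86.8% and 85.3% of the Piranha peaks in replicates 1 and 2, when peaks over a protein-coding and a lncRNA gene are included. Genes of small RNAs, mainly small nucleolar RNAs (snoRNAs), held 116 and 95 peaks, which is 5.16% (Wilson 95% interval 4.32 to 6.15) and 4.55% (3.74 to 5.54). The mitochondrial genome held 1.69% (1.23 to 2.31) and 2.54% (1.95 to 3.31), nuclear ribosomal RNA genes 1.82% (1.35 to 2.46) and 1.92% (1.41 to 2.60), and unplaced contigs 2.05% (1.54 to 2.72) and 2.30% (1.74 to 3.04). The contig peaks lay mainly on GL000220.1 (23 and 19) and KI270733.1 (22 and 29). Features on contigs were not assigned to genes, so the shares of the other classes, ribosomal RNA included, leave out any that lie there. None of the 10 classes differed between the Piranha replicates in two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, where the lowest adjusted p was 0.290. Among CIMS sites the protein-coding share was lower, at 71.4% and 71.7%, and pseudogenes held 18.3% (16.9 to 19.7) and 16.4% (14.9 to 18.1) of the sites against 0.801% and 1.44% of the Piranha peaks. The odds ratio of pseudogenes for CIMS over Piranha was 27.7 (17.2 to 44.4, Fisher's exact test, adjusted p = 2.63e-113) in replicate 1 and 13.5 (9.23 to 19.7, adjusted p = 5.61e-74) in replicate 2. No class differed between the CIMS replicates either, with a lowest adjusted p of 0.339. Reads shared between a gene and its pseudogene copies cannot be assigned from the lists, so pseudogene features are uncertain. Intervals cover counting error only.

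lncRNAs were a small part of the lists, and MALAT1 led them. MALAT1, an abundant nuclear lncRNA (gene 378938, chromosome 11, 65497738 to 65506516), carried 17 and 19 Piranha peaks and 12 and 5 CIMS sites in replicates 1 and 2. By number of peaks it ranked 13 of 680 and 11 of 619 genes. NEAT1, the lncRNA scaffold of paraspeckles (gene 283131, chromosome 11, 65422798 to 65445540), carried 6 and 5 peaks, which ranked 93 of 680 and 110 of 619, and 1 and 5 CIMS sites. Per kb of gene body, NEAT1 had 0.264 and 0.220 peaks and MALAT1 1.94 and 2.16.

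The peaks of NEAT1 fell at its ends. In replicate 1, 4 lay between 65422851 and 65424250 and 2 between 65444801 and 65445300, all on the plus strand with 11 to 15 tags per bin. In replicate 2, 4 lay between 65422951 and 65423700 and 1 at 65444801 to 65444850, with 12 to 16 tags. The peaks at 65423651 to 65423700 and at 65444801 to 65444850 were in both lists, where placements within the gene gave 0.068 shared peaks on average (one-sided permutation p = 0.002). Placement within 1000 bases of each peak and inside the gene, which keeps the clusters at the ends, gave 0.478 (permutation p = 0.0709), so recurrence beyond the clustering was not shown for NEAT1. Between 65424250 and 65444801 NEAT1 had no Piranha peak in either list. The gene body of the antisense transcript TALAM1 overlaps features of MALAT1. MALAT1 shared 9 of its 17 replicate 1 peaks, against 3.16 by chance (permutation p = 0.002) and 3.32 with placement near each peak (permutation p = 0.001, the smallest possible). No CIMS site of NEAT1 recurred and none lay in a NEAT1 peak, and 4 of the 5 sites in replicate 2 were deletions covered by 2 tags each, in 2 pairs of adjacent bases. All 12 and 5 CIMS sites of MALAT1 were deletions, and 4 bases recurred against 0.007 by chance (permutation p = 0.001, the smallest possible), 2 of them adjacent. Each base was counted as a site, although adjacent deletions can stem from the same event.

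**Figure D3:**
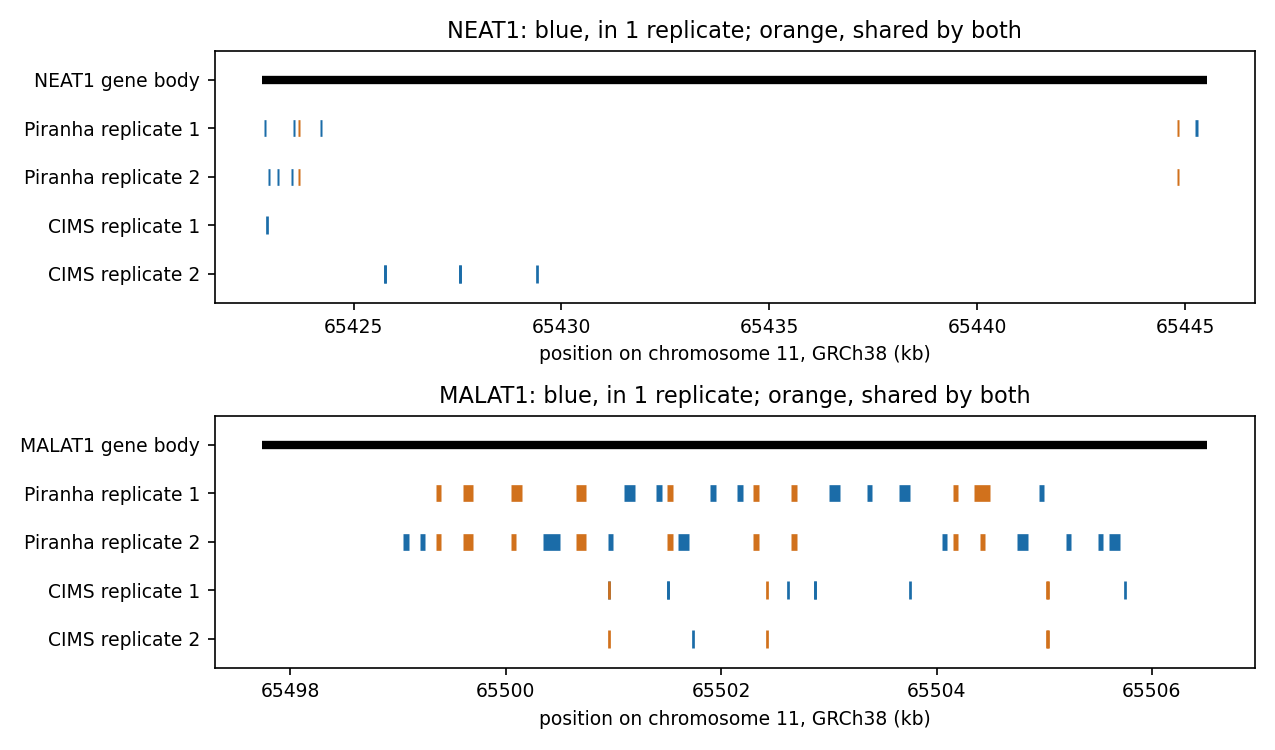
Positions of Piranha peaks (blocks) and CIMS sites (ticks) along the NEAT1 and MALAT1 gene bodies on chromosome 11 (x axis, kb, GRCh38), with 1 row per list. Orange features were in both replicates and blue ones in 1. The NEAT1 peaks lie at the ends of the gene, with 2 shared, and the MALAT1 peaks are spread along it, with 9 replicate 1 peaks shared.

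Few other lncRNAs had features in both replicates. Of the genes with peaks in both, 3 were lncRNAs, namely MALAT1, NEAT1 and the uncharacterised LOC105370062 on chromosome 12, with 2 and 2 peaks of up to 27 and 34 tags. When each overlapped gene was counted, 11 of the 40 lncRNAs of the list of nuclear and chromatin lncRNAs had peaks in both. For 8 of them, GAS5, SNHG1, SNHG6, SNHG16, SNHG17, SNHG29, DANCR and ZFAS1, peaks lay on a small RNA gene inside the lncRNA. H19 had 6 and 9 peaks, all of which also overlapped the gene body of MRPL23. The CIMS lists had sites in both replicates for these 3 and for LOC102724458, LOC124902983, LOC124904498, LOC107984893 and LOC107986070, uncharacterised lncRNAs without a Piranha peak and with 1 or 2 sites per replicate. Features in a lncRNA gene outside protein-coding genes made up 2.31% ± 0.122 (SD, n = 2 lists) of the Piranha peaks and 2.91% ± 0.481 (SD, n = 2 lists) of the CIMS sites. Whether the callers differed depended on the definition. For the shares above the odds ratio of CIMS over Piranha was 1.16 (0.805 to 1.67, Fisher's exact test, p = 0.463) in replicate 1 and 1.37 (0.946 to 1.98, p = 0.0964) in replicate 2. In the class order, which leaves to lncRNA genes only features outside small RNA genes, pseudogenes and the other classes ranked before them, they held 1.20% and 1.29% of the Piranha peaks and 2.11% and 2.78% of the CIMS sites, with odds ratios of 1.77 (1.12 to 2.80, Fisher's exact test, adjusted p = 0.0201) and 2.18 (1.38 to 3.45, adjusted p = 0.00100). Most of the 27 and 27 Piranha peaks in this class lay in MALAT1, NEAT1 and LOC105370062. Features of the same gene are not independent, so these tests describe the lists and do not show a difference across lncRNA genes. Counting a lncRNA gene even where a protein-coding gene overlapped it gave 8.87% and 8.65%, and counting each hit gene once gave 0.691% for Piranha and 2.91% for CIMS.

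The mRNAs of the study's own proteins had few or no listed features. SIN3A, and the luminal transcription factors GATA3 and ESR1, had no feature in any of the 4 lists. FOXN3 had no Piranha peak and 1 CIMS site, in replicate 2, with 2 mutated tags. The lists hold only features past the callers' thresholds, so this sets no limit on the RNA level.

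Among the 13 gene lists fixed before the data were examined, the fullest in the Piranha peaks were housekeeping ones. Of 19 cytoskeleton and glycolysis mRNAs, 10 had a peak in both replicates, among them FLNA with 13 and 19, ENO1 with 8 and 8, PKM with 9 and 7 and ACTB with 6 and 4. Of 19 heat-shock and protein-folding mRNAs, 7 did, led by the chaperone genes of the endoplasmic reticulum CANX (19 and 13), CALR (10 and 8), PDIA6 (12 and 6) and PDIA4 (10 and 5). Of 37 mitochondrial genes, 14 did, including ND5 (9 and 16), COX1 (5 and 5), CYTB (4 and 3) and ND6 (3 and 5). Of the ND6 peaks, 1 and 3 were on the minus strand, which encodes ND6. Of 26 epithelial junction and epithelial-mesenchymal transition mRNAs, 5 did, namely FN1, CD44 (8 and 9), ITGB1 (13 and 5), VIM (4 and 4) and JUP (2 and 2). The mRNAs of cytosolic ribosomal proteins had 11 of 85, among them RPS21 (2 and 3), RPS28 (2 and 2), RPL35A (1 and 2) and RPL38 (2 and 1).

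The other lists had smaller shares of members with peaks in both replicates. Translation factors had 4 of 64, EEF2, EEF1A2 (6 and 5), EIF4G1 (5 and 5) and PABPC1 (2 and 2). Paraspeckle and nuclear RNA-binding protein mRNAs had 2 of 31, HNRNPA2B1 (9 and 5) and HNRNPU (1 and 1), and histone mRNAs had 1 of 74, H1-2 (1 and 2). Nuclear and chromatin lncRNAs had 2 of 40, MALAT1 and NEAT1. Housekeeping small RNAs had 60 of 1394, among them RN7SK (1 and 1), SNORD17 (2 and 2), SNORD15A (1 and 2) and SCARNA10 (2 and 1). None of the 36 luminal and oestrogen-response mRNAs had a peak in both replicates, and 4, KRT8, KRT18, MYC and IGF1R, named after their values were seen, had one in a single replicate. The 25 mRNAs of the SIN3A complex and the 20 markers of blood, immune, stromal and endothelial cells had no peak in either replicate.

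Set against genes with a peak in either replicate, no list was enriched for peaks in both in one-sided Fisher's exact tests adjusted over the 26 tests. The lowest exact p was 0.0568, for the cytoskeleton and glycolysis list (odds ratio 3.79, 95% interval 0.825 to 17.4, adjusted p = 0.492), so 0 lists passed at an unadjusted 0.05 as well. Most lists had few members with a peak, so enrichment is not excluded for them. The heat-shock and protein-folding list had 8, with an odds ratio of 5.29 (95% interval 0.648 to 43.2, one-sided Fisher's exact p = 0.0796). Set against annotated protein-coding and lncRNA genes instead, with a peak in either replicate, 9 of the 13 lists passed for Piranha and 8 for CIMS. The odds ratio was then 79.4 (31.2 to 202.2, Fisher's exact test, adjusted p = 2.49e-15) for the cytoskeleton and glycolysis list and 5.73 (2.02 to 16.2, adjusted p = 0.0116) for the luminal list. The genes with a peak in the Piranha test were the 826 of any biotype, of which 649 were protein-coding or lncRNA genes. The CIMS test counted genes of any biotype likewise. These odds ratios are therefore too low, and the counts of passing lists are approximate. The annotated background also includes genes the cells need not express.

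CIMS sites named partly different genes. FN1 (11 and 7 sites), PIEZO1, a mechanosensitive channel gene (12 and 7), LAMA5, a laminin gene (8 and 11), ACTG1 (10 and 7), PTPRF (7 and 7), PSCA (8 and 10) and mitochondrial CYTB (8 and 9) were among the 10 genes with the most sites in both replicates. The others were the pseudogenes PDIA3P1 (10 and 9), PKMP1 (9 and 10) and HSP90B2P (7 and 9), none of which had a Piranha peak. Mitochondrial transcripts were the 1 enriched list, with 12 of the 18 genes with a site having one in both replicates (odds ratio 6.89, 95% interval 2.57 to 18.5, one-sided Fisher's exact test, adjusted p = 0.00219). They included ND5 (5 and 8), COX3 (5 and 3) and ND4 (5 and 4), and in the better-supported part of each list the count stayed at 12 of 18 while the share of other genes rose, with an odds ratio of 3.93 (1.46 to 10.5, one-sided Fisher's exact p = 0.00473, adjusted p = 0.123). Housekeeping small RNAs had sites in both replicates at 10 of 30 genes, with SNORD118, SNORD12B, SNORD65 and RNU5F-1 leading.

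For the remaining lists the members with CIMS sites in both replicates were few. They numbered 5 for the cytoskeleton and glycolysis list (FLNA, FLNB and MYH9 besides ACTG1 and LDHA), 4 for the nuclear RNA-binding protein list (HNRNPA2B1, MATR3, PTBP1 and SRSF2) and 3 for the junction list (FN1, ITGB1 and JUP). They numbered 2 each for protein folding (CANX and PDIA6), translation (EEF2 and EEF1A2) and nuclear lncRNAs (MALAT1 and NEAT1), and 1 each for ribosomal proteins (RPS16), histones (H1-10) and the luminal list (ADCY9, 3 and 1 sites). The SIN3A complex and the markers of other cell types had 0.

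The 5 shared sites with the highest lower number of mutated tags were substitutions. They lay in BSG (22 and 21 mutated tags of 23 and 22 covering tags), the pseudogene NME2P1 (17 of 17 and 18 of 18), DHFR (16 of 16 and 17 of 17), PSCA (20 of 21 and 15 of 16) and outside genes on chromosome 3 (17 of 17 and 15 of 15). Of the replicate 1 sites, 622 recurred at the same base and strand, which is 21.9% (Wilson 95% interval 20.4 to 23.4), and 28.9% (27.0 to 30.8) of the replicate 2 sites did. Placement within genes gave 0.0561% on average (one-sided permutation p = 0.001, the smallest possible). Of the 622, 621 had the same mutation type in both lists and 522 were substitutions in replicate 1. In 344 of the 622 (55.3%) every covering tag was mutated in both lists. Fixed differences from the reference or misplaced reads could also recur in this way, so recurrence alone does not show crosslinking. Among sites with at least 3 mutated tags, the share was 39.4%.

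From 2 to between 5 and 9 covering tags, recurrence rose from 1.09% to 53.2% in replicate 1 and from 0.958% to 70.6% in replicate 2. At 10 or more tags it was 69.4% and 63.9%, and the types differed in coverage. Over all coverages, substitutions recurred at 41.5% (38.8 to 44.2) of replicate 1 and 52.4% (49.3 to 55.5) of replicate 2 sites. Deletions recurred at 4.80% (3.57 to 6.42) and 4.02% (2.98 to 5.41), and 790 of 875 and 939 of 1020 of them were covered by 2 tags. At 3 to 4 covering tags substitutions recurred at 26.5% and 37.0% and deletions at 35.7% and 40.5% in replicates 1 and 2, and at 5 to 9 tags at 55.2% and 75.5% against 55.2% and 47.1%. At 10 or more tags they were 80.8% and 72.9% against 32.1% and 33.3%, with 17 to 37 deletions per value. A difference between types at equal coverage was not tested. Insertions were 710 sites in replicate 1 and 139 in replicate 2. The replicate 1 list included 531 insertions with 2 mutated tags and the replicate 2 list none, and those with at least 3 numbered 179 and 139.

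**Figure D4:**
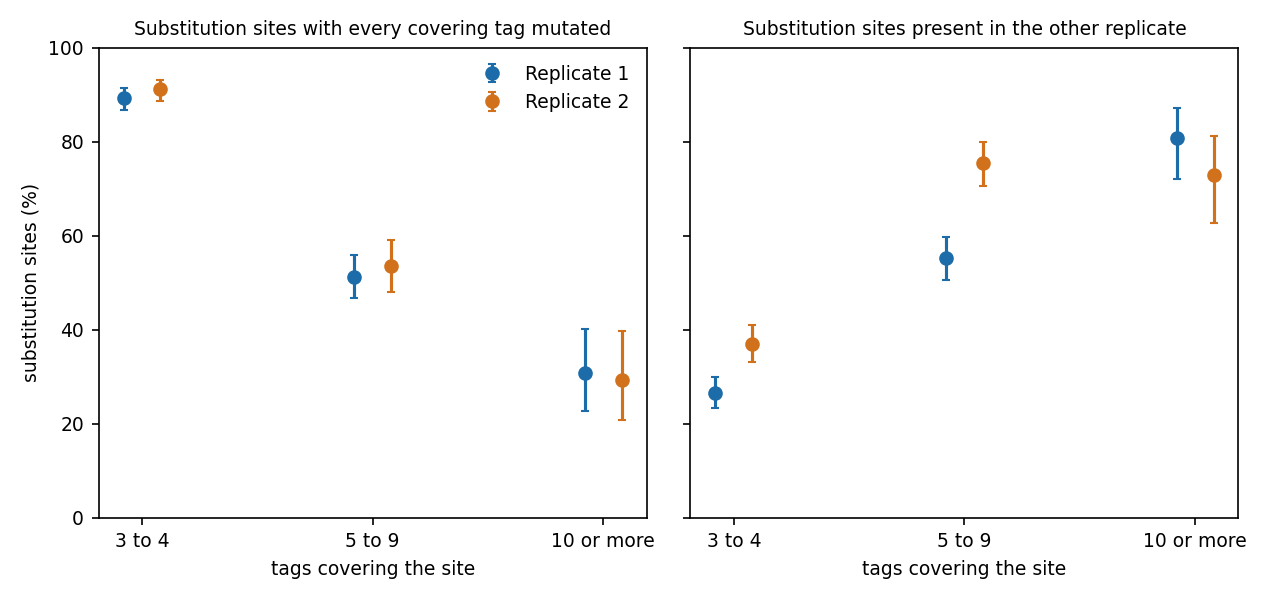
Substitution sites of the CIMS lists by number of covering tags (x axis), as the share in which every covering tag was mutated (left, percent) and the share present in the other replicate (right, percent), with Wilson 95% intervals. The fully mutated share was 89.3% and 91.2% at 3 to 4 covering tags and 30.8% and 29.4% at 10 or more. Listed substitutions had at least 3 mutated tags, so those covered by 3 tags were fully mutated by construction.

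At the level of genes, 1629 and 1293 genes had CIMS sites and 543 had them in both replicates, which is 33.3% and 42.0%. Over the genes that any list hit, as set before the data were examined, the odds ratio was 0.263 (0.224 to 0.308, two-sided Fisher's exact test, p = 1.47e-63), with 760 shared genes under independence. That background came mostly from the CIMS lists themselves, since 394 of its 2773 genes lacked a CIMS site. Over annotated protein-coding and lncRNA genes the odds ratio was 23.2 (20.1 to 26.7, Fisher's exact test, p = 3.00e-298), and over the 826 genes with a Piranha peak it was 9.32 (6.64 to 13.1, p = 1.14e-44), so the background changed the direction. Over the 2773 genes the odds ratio was 2.21 (1.78 to 2.74) for genes with at least 2 sites and 4.04 (3.39 to 4.82) in the better-supported part of each list. With these choices 1855 and 1537 of the 2773 genes were in neither list, so this change is not separate from the make-up of the background.

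The callers met at few positions but at shared genes. FN1, LAMA5, MALAT1 and PIEZO1 carried peaks and sites in both replicates, as did 178 genes of the 473 with peaks and 543 with sites in both (odds ratio 3.20, 2.57 to 3.97, Fisher's exact test, p = 2.45e-24). Of the CIMS sites, 151 (5.31%, Wilson 95% interval 4.55 to 6.20) in replicate 1 and 115 (5.34%, 4.46 to 6.37) in replicate 2 lay inside a Piranha peak of the same replicate. Random placement within genes gave 0.952% and 1.08%, so the shares were 5.58 and 4.94 times chance (one-sided permutation p = 0.001 each, the smallest possible). The placements ignored coverage and could fall in introns. Both callers need tags at a position, so an excess over these placements is largely built in and shows no further link between peaks and sites. MALAT1 had 3 of 12 and 1 of 5 of its sites in peaks. With peaks widened by 50 bases on either side the mean share was 9.61%.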

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

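The tests with placement within 1000 bases, the other caller's genes as background, a minimum of 3 mutated tags, sites with unmutated tags, merged consecutive bases, another class order for pseudogenes, any lncRNA gene and each overlapped gene were chosen after seeing the data. Sharing of Piranha peaks stayed above chance under each alternative run (47.8% to 60.0%), as did sharing of CIMS sites (21.9% to 39.4%) and CIMS sites in Piranha peaks (4.76% to 9.61%, and 5.31% to 5.34% leaving out a replicate), each with a permutation p of 0.001. None of these placements followed the coverage of the genes. The fold over chance moved further, from 10.3 to 4.49 for peaks within 50 bases. For CIMS sites it moved from 390 to 19.8 within 10 bases and to 631 with placement within 1000 bases. Gene sharing of the CIMS lists turned from an odds ratio of 0.263 to 23.2 over annotated genes, 2.21 with at least 2 sites per gene, 4.04 in the better-supported part and 9.32 over genes with Piranha peaks. The original background came mostly from the CIMS lists. The value also turned within that background with fewer sites counted, where 1855 genes (at least 2 sites) and 1537 genes (better-supported part) were in neither list, against 394. That turn is therefore not separate from the make-up of the background.

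The protein-coding share, in the order Piranha replicates 1 and 2 and CIMS replicates 1 and 2, moved to 81.1%, 79.2%, 67.5% and 67.9% with lncRNA genes before protein-coding ones. It moved to 85.3%, 83.0%, 63.8% and 63.7% weighted by score, and to 84.1%, 80.6%, 56.6% and 56.25% in the better-supported part of each list. With protein-coding genes before pseudogenes the CIMS shares were 77.5% and 77.6%. The lncRNA share moved to 0.691% for Piranha with genes counted once, and to 8.87% for Piranha and 8.65% for CIMS with any lncRNA gene. With genes counted once it was 2.91% for CIMS. Leaving out a replicate gave 2.22% to 2.40% for Piranha and 2.57% to 3.25% for CIMS. Enriched preset lists numbered 9 for Piranha and 8 for CIMS against annotated genes, with hit genes of any biotype counted. They numbered 0 for CIMS in the better-supported part, where 1 passed unadjusted. The sharing of NEAT1 peaks fell from 29.4 to 4.18 times chance with placement near each peak (permutation p = 0.0709), by construction since that keeps their clustering. In the better-supported part NEAT1 kept a mean of 3 peaks and 1 CIMS site, and its CIMS sites ranged from 1 to 5 leaving out a replicate. The cause was not tested, except that the better-supported part holds fewer features and the class orders move features by construction.

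No paired analysis was possible because the lists carry no antibody, so there is no FOXN3 list to set against an IgG list. Alternatives that need exons, a genome or gene strand were not run. Library depth is unknown, so what it limits was not measured. The lowest listed peak had 11 tags, and the median CIMS site was covered by 3 tags.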

Other observations

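Tests on symbol families, snoRNA families, pseudogene parents, the peak height ceiling, coverage-matched recurrence translation factors as a control and mesenchymal genes in the CIMS lists were chosen after their results or the lists had been seen. Extracellular matrix, adhesion and transporter genes were counted because several of them were among the genes with the most peaks, so the counts describe the same lists and test nothing. Of 79 integrin, laminin and collagen genes, 12 had Piranha peaks in both replicates, which is 15.2% against 1.81% of other protein-coding genes. They included ITGA5, COL5A1, LAMA5 (12 and 18 peaks), COL5A2 (12 and 13), ITGA3 (11 and 9) and COL4A2 (6 and 6). Of 386 solute carrier genes, 16 did (4.15%), led by SLC7A5 (16 and 20), SLC38A2 (17 and 14) and SLC3A2 (10 and 12). Proteasome subunits had 2 of 50 and kinesins 0 of 39. The families were not matched for expression or length.

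Among small RNAs, 39 of 357 box C/D snoRNA genes (10.9%, Wilson 95% interval 8.09 to 14.6) and 11 of 182 box H/ACA snoRNA genes (6.04%, 3.41 to 10.5) had peaks in both replicates. The odds ratio of H/ACA over C/D was 0.525 (0.262 to 1.05, Fisher's exact test, p = 0.0833), so a difference was not detectable. Mitochondrial peaks lay on both strands. Of 38 and 53 peaks, 18 and 21 were on the minus strand, where ND6 is the annotated mRNA by textbook knowledge, and 17 and 18 of these lay outside ND6. The mitochondrial ribosomal RNA genes RNR1 and RNR2 had no Piranha peak in either list and held 2 and 7 CIMS sites. Of 132 pseudogenes with CIMS sites in both replicates, 101 are named after a protein-coding gene, and for 32 of these (31.7%, 23.4 to 41.3) that gene had Piranha peaks in both, against 4.12% for the other pseudogenes so named. That count was prompted by pairs such as the following in the same lists. PKMP1 had 9 and 10 sites while PKM had 1 and 0 with 9 and 7 peaks, and PDIA3P1 had 10 and 9 while PDIA3 had none with 2 and 3 peaks.

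In 77.6% and 82.1% of CIMS sites every covering tag carried the mutation. This is fixed in advance for the 1198 and 939 sites covered by 2 tags. It is also fixed for substitutions covered by 3 tags, since listed substitutions had at least 3 mutated tags. A fall with coverage is therefore largely built in and decides nothing about low coverage. At 10 or more tags, where the outcome is not fixed, the share was 22.9% (Wilson 95% interval 16.8 to 30.4) and 20.5% (14.3 to 28.5). Both lay above the 20% set beforehand as the upper bound for low coverage. Both intervals include 20%, so whether the bound was passed is not resolved. Reads placed on a pseudogene copy are another candidate source for part, since pseudogenes held 42.6% and 36.5% of fully mutated sites covered by at least 5 tags (odds ratios 6.54 and 5.72), below the majority set beforehand. Fixed differences between the cells and the reference were predicted to make fully mutated substitutions recur more, but at 3 to 10 covering tags they did not (odds ratios 0.897, 95% interval 0.689 to 1.17, and 0.662, 0.485 to 0.903, one-sided Fisher's exact p = 0.809 and 0.997), which met the bound set beforehand against them. That bound was wrong because it mixed coverages, with a median of 3 tags for fully mutated sites against 6, and matching on coverage, chosen after that result, gave 2.68 and 3.29 (permutation p = 2e-05 each, the smallest possible). These explanations cannot be told apart, since the matched test does not decide either, as a fully mutated site has more mutated tags at equal coverage and is listed more easily, and no biological explanation was tested.

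Luminal mRNAs had Piranha peaks in either replicate at 4 of 36 genes (11.1%, Wilson 95% interval 4.41 to 25.3), fewer than several other lists. The share was larger than among annotated protein-coding and lncRNA genes, where 649 of 38353 had a peak. The odds ratio of 5.73 counted genes of any biotype with a peak, so it is too low. Low depth would be excluded by the bound set beforehand, since 63.2% of cytoskeleton and glycolysis mRNAs had a peak (odds ratio 13.7, Fisher's exact test, p = 0.000107), and folding (8 of 19) and ribosomal protein mRNAs (27 of 85) go the same way, whereas translation factors, a list set against them later, reached 9.38% (odds ratio against luminal 0.828, exact p = 0.744). That bound was wrong by design, because low depth spares abundant mRNAs first and the lists were not matched for abundance, so low depth stays open. RNA from cells other than the luminal line could also give the pattern, and mesenchymal mRNAs had peaks at 4 of 7 genes (FN1, VIM, CD44 and ITGB1, some of which luminal cells also express) against 1 of 10 epithelial ones (JUP; two-sided Fisher's exact p = 0.101), and CIMS sites at 5 of 7, with CDH2 as the fifth, against 1 of 10 (exact p = 0.0345, chosen after the peaks were seen). These cannot be told apart, since the genes are few and the lists give no expression levels. The 20 markers of blood, immune, stromal and endothelial cells had no Piranha peak, but they do not cover cancer cells of another line. No biological explanation was tested.

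No Piranha peak exceeded 41 tags per bin, although abundant RNAs such as RN7SK, MALAT1 and ribosomal RNA were listed. Counting each start position once could cap a bin at its 50 positions. The median tags of nuclear ribosomal RNA peaks were at most 1.31 times the median of protein-coding peaks, a flatness that low depth might also give. Single nuclear ribosomal RNA peaks reached 27 and 28 tags in replicates 1 and 2, against 41 and 39 for the highest of all peaks. Peaks on unplaced contigs were not assigned to any gene, so any ribosomal RNA peaks there are left out of these values. Contig peaks reached 30 and 35 tags, with medians at most 1.23 times that of protein-coding peaks. Leaving out the most covered regions is another candidate explanation, and RNR1 and RNR2, without a peak, held CIMS sites covered by up to 41 tags, but that is a count over a single base and not comparable with tags per bin, so it decides nothing. An earlier version of the test, on MALAT1 and RN7SK peaks, spoke against it and was replaced after it was seen, because MALAT1 peaks reached only 22 tags. That reason does not cover RN7SK, whose peak had 33 and 29 tags in replicates 1 and 2. These cannot be told apart, since the lists give neither duplicates nor excluded regions, and no biological explanation was tested.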
